A study of Homo sapiens with 58 samples.

How the data were processed

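Biotin-labelled cRNA from 48 human macrophage samples and 10 skin samples was hybridised to single-colour Illumina bead arrays of 48802 probes. Monocytes adhering from buffy-coat blood cells were cultured for 7 days with 50 ng/ml M-CSF, the macrophage growth factor, and treated for 24 h with 20 ng/ml IFN-γ, 25 ng/ml IL-4, 20 ng/ml TNF-α, 1 µg/ml LPS, or LPS plus IFN-γ. The labels give neither dose nor time for IL-17. By the ID given in the labels, skin came from 5 patients, each with 1 lesional and 1 non-lesional sample. The sample titles number the 10 skin samples separately, so the pairing by patient rests on that ID alone.

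The authors deposited a non-normalized table of bead intensity values with a detection p-value per probe and array, per the file headers, and a value table of log2 values, which the authors normalised between arrays with lumi (version not given). In the deposited log2 table each array had a median of 5.60 and the largest standard deviation of sorted values across arrays was 3.03e-04. Of 58 columns with deposited intensity values, 56 could be matched to samples by their labels. Each of the 56 correlated best with its own sample of the value table (r = 0.994 to 1.00, across probes, which are not independent). For 2 samples, 1 control and 1 LPS, the labels did not decide the column, so these samples entered through the value table only.

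The main values were made from the intensity table with neqc in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), which corrects background by the detection p-values, adds an offset of 16, normalises by quantiles and takes log2. Macrophage and skin arrays were normalised separately. Probes had to be detected (p under 0.05) on at least 5 arrays of a fit. The probe annotation gave 1 symbol for 28097 probes, several for 13 and none for 20692, and no symbol changed when 28058 of 28110 named probes were matched to the reference by gene ID. Probes of Y-linked genes and XIST (122) were left out of every table. Each gene was represented by the probe with the highest mean log2 signal, macrophages and skin weighted equally, which left 11893 genes tested in macrophages, 12266 in skin and 10447 in both. Median intensity per array was 41.4 to 55.1.

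Replicates are donors or patients. Of 6 macrophage donors 1 was run again for all 7 groups, and those 2 runs were averaged so that a donor counted once (r = 0.974 to 0.987 between the runs, across genes). Another donor had no control sample. The main model held group means only, without a block for the donor, because the labels name no paired method. Donor IDs do pair the samples, and a fit with the replicate as a block was run beside it. With group means removed, samples of the same donor correlated with a mean r of 0.27 to 0.66 per donor, across genes. For the 2 skin samples of a patient r was 0.17 to 0.61. The standard errors and p-values of the main fit do not use this pairing. Genes were tested with limma (lmFit and eBayes with a trend, two-sided, 32 residual degrees of freedom in macrophages and 8 in skin), adjusted by Benjamini-Hochberg over all genes of a comparison and called at an adjusted p under 0.05. Comparisons were each treatment against control, IFN-γ against IL-4, LPS plus IFN-γ against LPS and against IFN-γ, the interaction of LPS and IFN-γ, and lesional against non-lesional skin. Intervals are 1 standard error. Where array batch is a block, gene counts come from all arrays with the runs of a sample as a random block, and list values come from first runs. Donors are in part spread over batches, so values within batches share donors.

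Altogether 29 gene lists were written from general knowledge, namely responses to IFN-γ, type I interferon and IL-4, class I and class II antigen presentation, NF-κB, metallothioneins, resident macrophage receptors, sterol synthesis, cell cycle, heat shock, markers of other blood cells, and skin lists. Lists with enough measured members were tested with camera (inter-gene correlation 0.01, adjusted over the lists of a comparison: 15 in macrophages, 24 in skin), and again with an estimated correlation. Median, mean and test differed in sign for 14 of 174 list tests, none of which passed. Where both group means were undetected no fold is given, and against 1 undetected group the fold is a lower bound. Sets for the skin comparison were genes higher by 2-fold or more and called, with at least 5 in skin.

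Genes to be named were chosen by rule: the 6 highest and 6 lowest called log2 changes with the same sign in every donor or patient with both samples (4 and 4 for comparisons of 2 treatments), the 3 largest called members of each list with at least 3 called, 11 genes always reported, and the 5 largest called members of each set in skin. The text gives a part of them and says where a gene was picked after its values were seen. Groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were the deposited log2 table, no background correction, joint normalisation, no detection filter, a 2-fold threshold, the replicate block, each replicate left out, array batch as a block, either run of the repeated donor, only the groups compared, and for sets the top 100 genes, other set definitions and an estimated correlation. Fits without 2 libraries that stood apart, fits of the deposited log2 values on the same arrays, and sets from these fits or without other cells' genes were added after the data were seen.

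The fitting and testing were tested on simulated data with the same group sizes, in which 200 genes were set to change. Between 52.2% and 86.6% of genes set to change 2-fold were called, and 3.97% to 8.05% of the calls were false; genes were simulated independently, so correlated genes were not covered. A simulated list raised 1.5-fold was called by camera, and one left unchanged was not.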

Results

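Transcript levels were measured on 58 single-colour bead arrays, 48 from cultured human macrophages and 10 from skin of patients with psoriasis, an inflammatory skin disease. The labels give 7 macrophage groups, namely control, IL-17, IFN-γ, IL-4, TNF-α, LPS (bacterial lipopolysaccharide) and LPS plus IFN-γ, from 6 donors called replicates here. After the repeat arrays of 1 donor were averaged, the comparisons used 4 control, 5 LPS and 6 replicates of each other group, and 5 lesional against 5 non-lesional skin samples. Of 48802 probes, 14372 to 17069 were detected per macrophage array and 17762 to 20338 per skin array, and the number of arrays limits the precision. On the first principal component of the macrophage arrays, which held 41.6% of the variance, IFN-γ replicates lay between 36.8 and 69.9, LPS plus IFN-γ replicates between 38.0 and 69.0, and control replicates between −38.2 and −18.5. These ranges leave out 1 library labelled IFN-γ, which stood apart from its group there, as did 1 labelled LPS; on the IFN-γ response list the former lay within its group's range. Both stayed in all comparisons, and values without them are given beside the larger changes. Below, ± is the standard error of a log2 change, and list shifts were tested against all other genes first with a preset and then with an estimated correlation between the genes of a list.

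**Figure D1:**
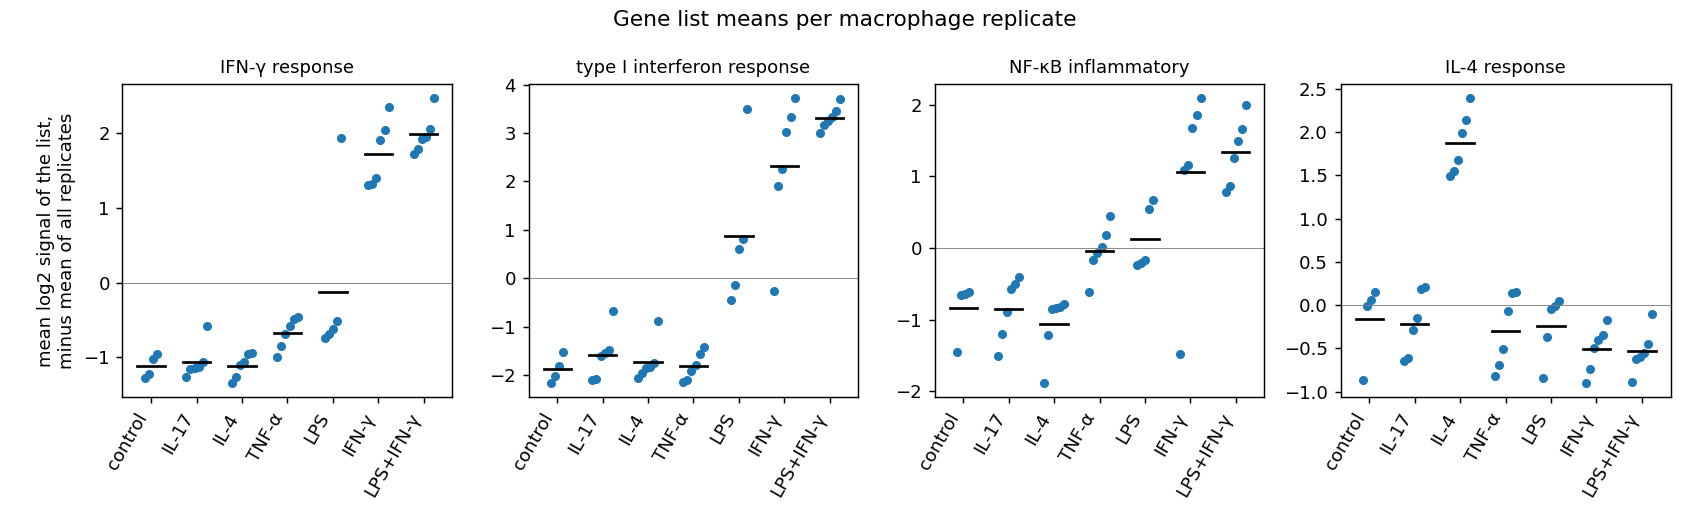
Each point is 1 macrophage replicate and each bar a group mean; the vertical axis is the mean log2 signal of a gene list, each gene centred on its mean over all replicates. On the IFN-γ response list the LPS group's other libraries lie between −0.73 and −0.52, those of the IFN-γ group between 1.30 and 2.35, and 1 LPS library lies near the latter.

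IFN-γ, the cytokine of classical macrophage activation, was compared with control (6 against 4 replicates) to find the genes it changes in 24 h. The chemokines CXCL9 and CXCL10 rose 239-fold (log2 7.90 ± 0.78, adjusted p = 2.29e-08) and 117-fold (6.87 ± 0.91, adjusted p = 3.08e-06). IDO1, which breaks down tryptophan, rose 114-fold (6.84 ± 1.04, adjusted p = 3.19e-05). Of 22 measured IFN-γ response genes 14 rose (17 when adjusted over the list alone). All 23 type I interferon response genes rose (23 adjusted over the list alone), IFI27 and IFI44L by 156-fold (7.28 ± 0.84, adjusted p = 4.33e-07) and 80.0-fold (6.32 ± 0.61, adjusted p = 1.83e-08). In the class I antigen processing list 9 of 17 genes rose (14 adjusted over the list alone), with the peptide transporter TAP1 up 3.84-fold (1.94 ± 0.25, adjusted p = 2.02e-06). Of 35 NF-κB inflammatory genes 18 rose (25 adjusted over the list alone), among them EBI3, a cytokine subunit, by 48.8-fold (5.61 ± 1.07, adjusted p = 6.58e-04) and IL6 by 30.04-fold (4.91 ± 1.44, adjusted p = 0.0238). Of 7 metallothioneins, metal-binding proteins, 6 rose (7 adjusted over the list alone), MT1M by 37.5-fold (5.23 ± 1.08, adjusted p = 0.00158). Leaving out the 2 libraries that stood apart raised IDO1 to 276-fold, IFI27 to 251-fold, EBI3 to 99.1-fold, IL6 to 78.6-fold and MT1M to 79.6-fold.

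Genes that fell with IFN-γ included PPARG, a lipid-sensing nuclear receptor (−2.50 ± 0.56, adjusted p = 0.00336, or −3.17 without the 2 libraries), the scavenger receptor COLEC12 (−3.42 ± 1.09, adjusted p = 0.0363), and HAMP, which encodes the iron hormone hepcidin (−3.18 ± 0.93, adjusted p = 0.0236). The serine synthesis enzymes PHGDH (−2.82 ± 0.80, adjusted p = 0.0194) and PSAT1 (−2.44 ± 0.74, adjusted p = 0.0275) fell too. IL23A, a subunit of IL-23, rose 4.10-fold (2.03 ± 0.53, adjusted p = 0.0111). IL12B was at least 3.27-fold higher (adjusted p = 0.0346) against controls in which it was not detected. None of 14 class II antigen presentation genes passed (0 adjusted over the list alone; median log2 change −0.44, adjusted p = 0.438). HLA-DRA (0.02 ± 0.11, adjusted p = 0.936), CD163 (0.20 ± 1.02, adjusted p = 0.932), CD68 (−0.06 ± 0.10, adjusted p = 0.768) and TNF (1.09 ± 0.82, adjusted p = 0.433) did not pass either.

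In total 605 genes rose and 710 fell under IFN-γ (limma, 11893 genes tested). Of these 352 and 204 changed by 2-fold or more (527 and 444 without the 2 libraries that stood apart). Median log2 changes were 2.61 for the IFN-γ response list (adjusted p = 1.34e-21, and 0.00108 with an estimated correlation), 3.84 for the type I list (2.19e-46 and 0.00329) and 0.87 for class I (3.86e-16 and 0.00329). They were 1.52 for NF-κB (2.14e-17 and 0.0222) and 3.42 for metallothioneins (4.62e-07, but adjusted p = 0.120 with an estimated correlation, or 0.0361 without the 2 libraries, where the median was 4.77). The count of 1315 genes was 2564 without the 2 libraries that stood apart, 1314 of them shared, and 2690 with the replicate as a block. With array batch as a block it was 2275 and the IFN-γ, type I and NF-κB list medians were 2.48, 3.77 and 1.65. Within the 3 batches that held both groups the IFN-γ list medians were 2.69, 2.85 and 3.40; some donors lay in more than 1 batch, so the batches are not separate replications here or below. Fitting only these groups gave 225 genes, and leaving out 1 replicate at a time gave 308 to 2554.

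IL-4, the cytokine of alternative activation, was compared with control in the same way (6 against 4 replicates). MAOA, which oxidises amines, rose 31.03-fold (log2 4.96 ± 0.76, adjusted p = 1.07e-04), FCER2, the low-affinity IgE receptor, 14.9-fold (3.90 ± 0.67, adjusted p = 6.81e-04). IL17RB, a receptor for IL-25, rose 10.8-fold (3.44 ± 0.79, adjusted p = 0.0192) and RAMP1, a partner of the calcitonin-like receptor, 10.2-fold (3.35 ± 0.21, adjusted p = 1.15e-13). Of 28 IL-4 response genes 15 rose and 0 fell (20 rose adjusted over the list alone). CD200R1, a receptor of an inhibitory ligand, was at least 1.58-fold higher (adjusted p = 0.0370), its controls being undetected. Among the genes that fell were SOD2, the mitochondrial superoxide dismutase (−1.30 ± 0.32, adjusted p = 0.0337), the cholesterol exporter ABCA1 (−1.19 ± 0.29, adjusted p = 0.0321) and the cell cycle inhibitor CDKN2B (−1.50 ± 0.37, adjusted p = 0.0361). The chemokine gene CCL22 was 5.39-fold higher (2.43 ± 1.10) without passing (adjusted p = 0.673; adjusted p = 0.0336 with the replicate as a block). CXCL9 (0.47 ± 0.78) and HLA-DRA (0.13 ± 0.11) did not pass (adjusted p = 1.00 for both).

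In all, 99 genes rose and 11 fell with IL-4. The IL-4 response list had a median log2 change of 1.84 (adjusted p = 8.95e-44, and 4.35e-08 with an estimated correlation). Metallothioneins (median −1.10, adjusted p = 0.0225), cell cycle genes (−0.33, adjusted p = 0.00701) and heat shock genes (0.31, adjusted p = 0.0185) passed with the preset correlation only (adjusted p = 0.815, 0.815 and 0.705 with an estimated correlation). No member of these 3 lists was called (0 adjusted over the list alone). With the replicate as a block 3 lists passed with the preset correlation, 2 higher and 1 lower, against 4 in the main fit, 2 higher and 2 lower. The count of 110 was 269 with the replicate as a block, 57 when only these groups were fitted and 38 to 117 when 1 replicate was left out. Taking array batch as a block gave 162, the IL-4 list median was 1.98, and metallothionein and heat shock lists no longer passed (adjusted p = 0.340 for both). Within the 3 batches with both groups the IL-4 list medians were 1.81, 1.71 and 1.86.

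LPS was compared with control (5 against 4 replicates). Every one of the 19 called genes rose, and 14 of them belong to the type I interferon list. IFI44L rose 27.7-fold (log2 4.79 ± 0.64, adjusted p = 8.71e-05), IFI27 25.2-fold (4.65 ± 0.87, adjusted p = 0.0119), and IFIT1, which binds foreign RNA, 15.2-fold (3.92 ± 0.73, adjusted p = 0.0119). The antiviral GTPase MX1 rose 9.50-fold (3.25 ± 0.65, adjusted p = 0.0176). Leaving out the 2 libraries that stood apart lowered IFI44L to 16.7-fold, IFI27 to 11.6-fold and IFIT1 to 8.80-fold. Of 23 type I genes 14 rose (23 adjusted over the list alone), of 17 class I genes 1 (5 adjusted over the list alone). None of 22 IFN-γ response, 35 NF-κB or 7 metallothionein genes was called (8, 4 and 7 adjusted over the list alone). TNF (0.79 ± 0.85) and CXCL9 (1.84 ± 0.81, or 0.41 without the 2 libraries) did not pass (adjusted p = 0.991 for both).

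The type I list had a median log2 change of 2.76 (adjusted p = 7.95e-73, and 6.10e-04 with an estimated correlation). Medians were 0.95 for the IFN-γ list (6.61e-11 and 0.0182), 0.43 for class I (1.74e-13 and 0.0119), 0.70 for NF-κB (5.05e-15 and 0.0359) and 2.71 for metallothioneins (1.92e-10 and 0.0359). Class II genes had a median of −0.49 and 0 of 14 called (0 adjusted over the list alone; adjusted p = 0.0378), which was lost with an estimated correlation (adjusted p = 0.575). Without the 2 libraries that stood apart 24 genes were called, 16 of them shared, and the class II list did not pass (adjusted p = 0.583). Medians were then 0.16 for the IFN-γ, 0.23 for the class I, 2.01 for the type I and 1.70 for the metallothionein list. With the replicate as a block the IFN-γ list had adjusted p = 0.0723 with an estimated correlation. With array batch as a block and runs as a random block 19 genes were called, 18 of them shared, and 13 belong to the type I list. Over first runs alone a batch block left 5 genes, all 5 of the type I list, whose median was 2.61. Within 3 batches the type I medians were 1.62, 1.82 and 2.72. Fitting only these groups gave 0 genes (limma; 507 in the full fit at unadjusted p under 0.05), and leaving out 1 replicate gave 1 to 20.

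LPS plus IFN-γ was compared with control (6 against 4 replicates). IFI27 rose 357-fold (log2 8.48 ± 0.84, adjusted p = 7.99e-09), CXCL10 284-fold (8.15 ± 0.91, adjusted p = 6.42e-08). IDO1 rose 274-fold (8.10 ± 1.04, adjusted p = 7.84e-07) and CCL5, a T cell chemokine, 53.6-fold (5.74 ± 0.91, adjusted p = 2.10e-05). Of the IFN-γ list 17 of 22 genes rose (18 adjusted over the list alone), of the type I list 23 of 23 (23 adjusted over the list alone), of class I 12 of 17 (16 adjusted over the list alone). Of NF-κB genes 23 of 35 rose (24 adjusted over the list alone) and of metallothioneins 7 of 7 (7 adjusted over the list alone). COLEC12 (−4.87 ± 1.09, adjusted p = 0.00127), PPARG (−3.48 ± 0.56, adjusted p = 2.71e-05) and the flagellin receptor TLR5 (−3.26 ± 0.67, adjusted p = 5.87e-04) fell. Of 14 class II genes 3 fell and 1 rose (5 and 1 adjusted over the list alone), including the peptide loading factor HLA-DMB (−2.33 ± 0.51, adjusted p = 0.00101). The list as a whole did not pass (median −0.66, adjusted p = 0.109). Among resident macrophage receptors SIGLEC1, a sialic acid receptor, rose 9.94-fold (3.31 ± 0.46, adjusted p = 2.61e-06) and LILRB5 fell (−2.29 ± 0.77, adjusted p = 0.0262). In the cell cycle list the replication factor MCM2 fell (−1.35 ± 0.27, adjusted p = 3.84e-04).

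This comparison called 1307 genes higher and 1657 lower. Median log2 changes were 2.82 for the IFN-γ list (adjusted p = 4.50e-16, and 0.00683 with an estimated correlation), 5.06 for type I (9.31e-41 and 0.00936), 1.08 for class I (3.57e-13 and 0.00936). They were 1.68 for NF-κB (2.14e-14 and 0.0446) and 4.50 for metallothioneins (1.05e-06, but adjusted p = 0.138 with an estimated correlation). With the replicate as a block the NF-κB list had adjusted p = 0.0758 with an estimated correlation. Batch as a block gave 3131 genes, and the IFN-γ, type I and NF-κB medians were 2.57, 4.73 and 1.70. Within 3 batches the type I medians were 4.97, 4.56 and 5.26.

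TNF-α, an inflammatory cytokine, was compared with control (6 against 4 replicates) and limma called 0 genes. At unadjusted p under 0.05 there were 470 genes (993 with the replicate as a block), where 594.65 were expected by chance. TNFRSF9, a co-stimulatory receptor and the gene with the smallest p, was 4.08-fold higher (log2 2.03 ± 0.38, adjusted p = 0.0525). TNFAIP6, a matrix-binding protein, was 8.88-fold higher (3.15 ± 0.92, adjusted p = 0.540). Without the 2 libraries that stood apart 17 genes rose, among them TNFRSF9 (adjusted p = 0.0122), TNFAIP6 (adjusted p = 0.0129) and GCH1, an enzyme of tetrahydrobiopterin synthesis (2.89-fold, adjusted p = 0.0129), picked after their values were seen. With the replicate as a block 5 genes rose, also picked after their values were seen: CLEC4E, ITPR3, JAG1, TNFRSF4 and TNFRSF9. TNF itself (0.70 ± 0.82), CXCL9 (0.41 ± 0.78) and IL23A (0.50 ± 0.53) did not pass (adjusted p = 1.00 for all). The submitters' value table with its 2 added samples gave 1 gene (0 on the same arrays), the second runs 1, array batch as a block 0, and leaving out 1 replicate 0 to 9.

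Of 35 NF-κB genes 0 were called with TNF-α (4 adjusted over the list alone), though 32 were higher (median 0.60, adjusted p = 1.88e-13; adjusted p = 0.200 with an estimated correlation, and 0.00529 without the 2 libraries). IFN-γ response genes had a median of 0.37 (0 of 22 called, 1 adjusted over the list alone; adjusted p = 0.00115, and 0.407 with an estimated correlation, or 0.0248 without the 2 libraries). Class I (0.22), metallothionein (1.16), cell cycle (0.26) and resident receptor (−0.58) lists passed with the preset correlation (adjusted p = 1.18e-04, 2.56e-04, 3.18e-04 and 0.0161) but not with an estimated one (adjusted p = 0.407, 0.407, 0.649 and 0.649). Adjusted over the list alone they held 1, 0, 0 and 0 called genes. Within the 3 batches that held both groups the NF-κB medians were 1.02, 0.62 and 0.65. With array batch as a block the median was 0.71 (adjusted p = 0.178 with an estimated correlation) and the cell cycle list no longer passed (adjusted p = 0.0776).

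IL-17, a T cell cytokine central to psoriasis, was compared with control (6 against 4 replicates) and limma called 0 genes. At unadjusted p under 0.05 there were 99 genes (209 with the replicate as a block), where 594.65 were expected by chance. Each alternative fit gave 0 genes as well. The cell cycle list was higher, with 19 of 19 members positive and 0 called (0 adjusted over the list alone; median 0.56, adjusted p = 1.11e-18). It was not so with an estimated correlation (adjusted p = 0.0967, and 0.0414 without the 2 libraries). Its median was 0.26, 0.37 and 0.64 within the 3 batches that held both groups, and 0.34 with array batch as a block (adjusted p = 0.716 with an estimated correlation). Type I interferon genes had a median of 0.31 (adjusted p = 0.00653; 0 of 23 called, 0 adjusted over the list alone), lost with an estimated correlation (adjusted p = 0.984) and with array batch as a block (adjusted p = 0.243). Within the batches the medians were −0.03, 0.19 and 1.61. CD163 (0.65 ± 1.02), CCL22 (0.67 ± 1.10) and MX1 (0.53 ± 0.63) did not pass (adjusted p = 1.00 for all). In simulated data of this design, with 200 genes set to change at once, 80.6% of those set to change 2-fold and 32.8% of those set to change 1.5-fold were called. The adjusted threshold is stricter where few genes change, so these shares do not give the chance of seeing a response of few genes.

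IFN-γ was set against IL-4 (6 against 6 replicates) to contrast both activation states. CXCL9 was 173-fold higher (log2 7.43 ± 0.70, adjusted p = 1.77e-09) and IDO1 120-fold higher (6.91 ± 0.93, adjusted p = 1.38e-06; 290-fold without the 2 libraries) with IFN-γ. MAOA (−4.66 ± 0.68, adjusted p = 4.82e-06), the lectin CLEC10A (−4.27 ± 0.52, adjusted p = 2.10e-07) and IL17RB (−4.22 ± 0.71, adjusted p = 4.21e-05) were lower. Of 28 IL-4 response genes 22 were lower (23 adjusted over the list alone; median −2.61, adjusted p = 8.60e-17, and 4.22e-04 with an estimated correlation). Higher were 16 of 22 IFN-γ list genes (18 adjusted over the list alone; median 2.78, 2.08e-17 and 0.00214), 22 of 23 type I genes (23 adjusted over the list alone; 3.60, 2.62e-36 and 0.0110). So were 9 of 17 class I genes (11 adjusted over the list alone; 0.78, 2.35e-11 and 0.0145) and 22 of 35 NF-κB genes (25 adjusted over the list alone; 1.89, 8.60e-17 and 0.0210). All 7 metallothioneins were higher (7 adjusted over the list alone; median 4.91, adjusted p = 5.04e-09, but adjusted p = 0.0504 with an estimated correlation, or 0.0180 without the 2 libraries). Of 7 natural killer cell markers 1 was higher (3 adjusted over the list alone; median 1.04, adjusted p = 0.0493, and 0.251 with an estimated correlation, or 0.0579 without the 2 libraries).

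Between IFN-γ and IL-4 1094 genes were higher and 1411 lower, and 3409 genes passed without the 2 libraries. With the replicate as a block 3962 passed, and the NF-κB list had adjusted p = 0.0570 with an estimated correlation. With array batch as a block 3339 passed and the IL-4, IFN-γ and type I medians were −2.50, 2.77 and 3.49. Within 4 batches the IL-4 list medians were −2.02, −2.41, −2.46 and −2.74. Fitting only these groups gave 1667 genes, and leaving out 1 replicate gave 1251 to 3098.

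LPS plus IFN-γ was set against LPS alone (6 against 5 replicates), which shows what IFN-γ added to LPS. CXCL9 was 68.9-fold higher (log2 6.11 ± 0.73, adjusted p = 7.42e-06), the antiviral membrane protein gene IFITM1 23.1-fold (4.53 ± 0.86, adjusted p = 0.00166) and ACOD1, which makes itaconate, 21.5-fold (4.43 ± 1.01, adjusted p = 0.00661). PPARG (−2.43 ± 0.52, adjusted p = 0.00431), TLR5 (−2.26 ± 0.63, adjusted p = 0.0231) and ATP6V0D2, a proton pump subunit (−1.91 ± 0.47, adjusted p = 0.01003), were lower. Of the IFN-γ list 14 of 22 genes were higher (16 adjusted over the list alone; median 1.84, adjusted p = 1.25e-17, and 0.00397 with an estimated correlation). Of type I genes 22 of 23 were higher (23 adjusted over the list alone; 2.30, 3.25e-25 and 0.0470) and of class I 7 of 17 (10 adjusted over the list alone; 0.67, 9.36e-10 and 0.0470). The NF-κB list had 10 of 35 higher (15 adjusted over the list alone; 1.05, adjusted p = 1.23e-09) and metallothioneins 1 of 7 (1 adjusted over the list alone; 1.67, adjusted p = 0.00341), both lost with an estimated correlation (adjusted p = 0.152 and 0.485, or 0.0258 and 0.316 without the 2 libraries). Without them IFITM1 was 57.0-fold higher, and TLR5 and ATP6V0D2 changed by −2.88 and −2.57.

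The count was 544 genes higher and 470 lower, and single libraries moved it. Without the 2 libraries that stood apart it was 2560 instead of 1014. CXCL9 was then 186-fold and ACOD1 64.4-fold higher, and the IFN-γ list median was 2.53. With the replicate as a block it was 2345, and the type I and class I lists had adjusted p = 0.146 and 0.0849 with an estimated correlation. With array batch as a block it was 1308, and those lists had medians of 2.28 and 0.54 (adjusted p = 0.0562 for both with an estimated correlation). Within the 4 batches the IFN-γ list medians were 2.47, 1.86, 2.32 and 0.07, and in the last, with 1 array per group, 50.5% of the called genes had the sign of the whole comparison. The LPS array of that batch was the LPS library that stood apart. Fitting only these groups gave 2 genes, and leaving out 1 replicate 89 to 2219. The submitters' value table, which adds 1 control and 1 LPS sample, gave 1595, but 995 on the same arrays.

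LPS plus IFN-γ was also set against IFN-γ alone (6 against 6 replicates), which shows what LPS added. Limma called 0 genes, with 350 at unadjusted p under 0.05, and each alternative fit gave 0 genes. In the type I list 23 of 23 genes were higher (median log2 change 1.01, adjusted p = 1.74e-16; 0 called, 0 adjusted over the list alone), lost with an estimated correlation (adjusted p = 0.251), and the median was 0.51 without the 2 libraries. T cell markers (0.32, adjusted p = 0.00199), natural killer cell markers (0.53), NF-κB (0.23), metallothionein (0.85) and class I (0.22) lists were higher and class II (−0.20) and cell cycle (−0.24) lists lower (adjusted p = 0.0213 for the last 6). In each 0 genes were called (0 adjusted over the list alone), and none passed with an estimated correlation (adjusted p = 0.251, 0.411, 0.544, 0.544, 0.544, 0.544 and 0.555). Without the 2 libraries the type I and T cell lists alone passed with the preset correlation, and the NF-κB, metallothionein and cell cycle medians were −0.07, −0.21 and 0.03. Within the 4 batches the type I medians were 0.49, −0.34, −0.19 and 2.42. In the last batch 1 LPS plus IFN-γ array was set against 2 IFN-γ arrays, 1 of them the IFN-γ library that stood apart. With array batch as a block the median was 0.86 (adjusted p = 0.575 with an estimated correlation). There the class I, cell cycle, T cell and natural killer lists no longer passed (adjusted p = 0.257, 0.0522, 0.955 and 0.955).

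Whether the IFN-γ effect differed with and without LPS was tested as an interaction of the 4 groups. Limma called 0 genes, with 134 at unadjusted p under 0.05. The IFN-γ effect on the type I list was smaller with LPS than without by a median log2 change of −1.64 (0 of 23 called, 12 adjusted over the list alone; adjusted p = 1.27e-40, and 0.0194 with an estimated correlation). IFN-γ (−0.57), class I (−0.29), NF-κB (−0.52) and metallothionein (−1.72) lists were also lower with the preset correlation (adjusted p = 6.04e-08, 8.60e-09, 1.51e-09 and 4.00e-06; 0 called and 0 adjusted over the list alone) but not with an estimated one (adjusted p = 0.0642, 0.0642, 0.144 and 0.172). Without the 2 libraries 1 gene was called, IFI44L, picked after its values were seen (−3.52 ± 0.58, adjusted p = 0.00996, against −3.73 ± 0.84, adjusted p = 0.989, with them). The type I shift was then −1.46 and the NF-κB shift −0.73 (adjusted p = 0.00183 and 0.00673 with an estimated correlation), the IFN-γ shift −0.24 and the class I shift −0.27 (adjusted p = 0.200 and 0.284 with an estimated correlation).

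Lesional skin was compared with non-lesional skin of the same patients (5 against 5 samples, not paired in the main fit), to describe the psoriatic transcriptome. TCN1, a vitamin B12 binding protein, rose 42.0-fold (log2 5.39 ± 0.75, adjusted p = 3.63e-04), the protease inhibitor SERPINB4 38.1-fold (5.25 ± 0.67, adjusted p = 2.33e-04). S100A12 rose 27.5-fold (4.78 ± 0.40, adjusted p = 2.52e-05) and CXCL8, a neutrophil chemokine, 24.4-fold (4.61 ± 1.12, adjusted p = 0.00889). Of 21 keratinocyte activation genes 20 rose (21 adjusted over the list alone; median 3.93). Of 10 genes of the IL-17 and IL-23 axis 8 rose (9 adjusted over the list alone; 2.42), such as LCN2 and IL36G by 15.29-fold (3.93 ± 0.54, adjusted p = 3.15e-04) and 9.07-fold (3.18 ± 0.33, adjusted p = 7.16e-05). Of 19 cell cycle genes 17 rose (19 adjusted over the list alone; 1.19). Of 22 type I interferon genes 21 rose (22 adjusted over the list alone; 2.03), OASL by 10.1-fold (3.33 ± 0.41, adjusted p = 1.75e-04). Of 17 IFN-γ response genes 13 rose (13 adjusted over the list alone; 0.85), GBP5 by 3.83-fold (1.94 ± 0.46, adjusted p = 0.00786). T cell genes rose in 8 of 12 (9 adjusted over the list alone; 1.06), with the cytotoxic protease GZMB up 5.38-fold (2.43 ± 0.37, adjusted p = 5.66e-04). Dendritic cell genes rose in 5 of 11 (6 higher and 2 lower adjusted over the list alone; 0.73), with LAMP3 up 2.36-fold (1.24 ± 0.16, adjusted p = 2.42e-04).

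In the sebaceous lipid list 14 of 15 genes fell in lesional skin (14 adjusted over the list alone; median −1.98), the neuropeptide GAL by 4.18 on the log2 scale (± 0.55, adjusted p = 2.71e-04) and the fatty acid elongase ELOVL3 by 3.49 (± 0.22, adjusted p = 4.84e-06). All 9 muscle and sweat gland genes fell (9 adjusted over the list alone; −1.98), among them the sweat peptide DCD (−2.25 ± 0.36, adjusted p = 7.82e-04). So did 8 of 9 adipocyte genes (9 adjusted over the list alone; −1.52), such as the fatty acid carrier FABP4 (−1.76 ± 0.37, adjusted p = 0.00385). Terminal epidermal genes fell in 5 of 12 (5 adjusted over the list alone; −0.48), with the barrier protein gene FLG2 at −1.59 ± 0.23 (adjusted p = 4.17e-04). Endothelial genes fell in 3 of 9 (1 higher and 6 lower adjusted over the list alone; −0.73). BTC, a growth factor of the EGF family, fell as well (−3.00 ± 0.16, adjusted p = 1.94e-06). Of 23 NF-κB genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; 0.37), of 17 class I genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; 0.41). Of 24 IL-4 response genes 2 rose and 7 fell (3 and 8 adjusted over the list alone; −0.24), and of 13 class II genes 1 rose (1 adjusted over the list alone; 0.38). TNF rose 1.60-fold (0.68 ± 0.15, adjusted p = 0.00549). CD163 (−0.15 ± 0.47, adjusted p = 0.840), CD68 (0.11 ± 0.17, adjusted p = 0.655) and HLA-DRA (0.70 ± 0.34, adjusted p = 0.149, or 0.00259 with the patient as a block) did not pass.

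**Figure D2:**
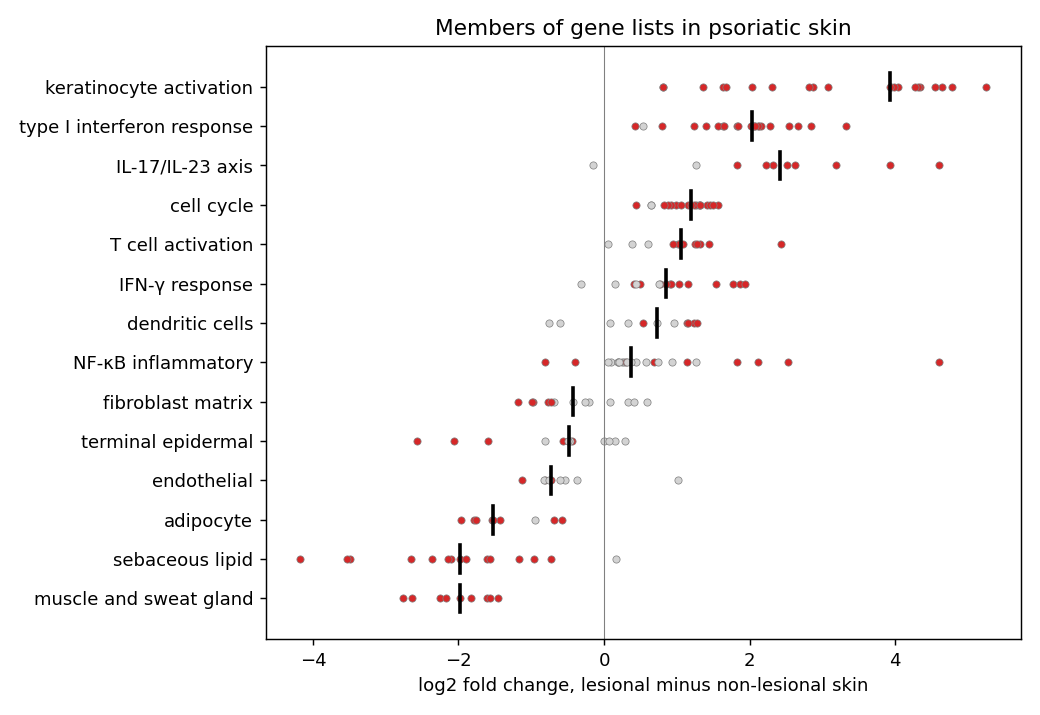
Each point is 1 gene, placed by its log2 fold change between lesional and non-lesional skin (5 against 5 samples), red where its adjusted p is under 0.05 and grey otherwise; each bar is the median of the list's measured genes. Medians run from 3.93 for keratinocyte activation to −1.98 for muscle and sweat gland genes.

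In skin 1609 genes rose and 1881 fell (limma, 12266 genes tested), 423 and 418 of them by 2-fold or more. Of 24 lists tested 15 passed with the preset correlation, but none with an estimated one (lowest adjusted p = 0.138), so the list statements rest on the counts and the preset test. Adjusted p with the preset correlation and then with an estimated one was 9.14e-16 and 0.138 for keratinocyte activation, 3.77e-06 and 0.227 for the IL-17 and IL-23 axis, 4.70e-11 and 0.240 for cell cycle. It was 6.71e-17 and 0.138 for type I, 1.90e-06 and 0.240 for IFN-γ response, 2.64e-04 and 0.414 for T cells, and 0.00683 and 0.255 for dendritic cells. It was 4.70e-11 and 0.138 for sebaceous lipid, 3.77e-06 and 0.138 for muscle and sweat gland, 3.49e-04 and 0.373 for adipocyte, 0.0141 and 0.4925 for terminal epidermal. It was 0.0254 and 0.532 for endothelial, 0.00182 and 0.414 for NF-κB and 0.00192 and 0.472 for class I genes. IL-4 response genes (adjusted p = 0.264) and class II genes (adjusted p = 0.0834, or 0.0114 with the patient as a block, lost there too with an estimated correlation at 0.4999) did not pass as lists. All skin arrays shared 1 batch, and leaving out 1 patient gave 2156 to 3988 genes. With the patient as a block 5234 genes passed, 2404 higher and 2830 lower, and 3484 were shared with the main fit.

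The genes that each treatment raised in macrophages by 2-fold or more were then followed in lesional skin, the comparison of macrophage responses with psoriasis that the study names as its purpose. Of 19 genes raised by LPS 16 were higher and 0 lower in lesional skin, with ISG15, a ubiquitin-like antiviral protein, up 6.31-fold (log2 2.66 ± 0.44, adjusted p = 9.59e-04) and MX1 up 5.85-fold (2.55 ± 0.19, adjusted p = 1.46e-05). Of 308 genes raised by IFN-γ 128 were higher and 29 lower, led by S100A12, OASL, IL36G, HERC6 (7.45-fold, 2.90 ± 0.26, adjusted p = 2.86e-05) and OAS2 (7.17-fold, 2.84 ± 0.29, adjusted p = 6.01e-05). Of 546 raised by LPS plus IFN-γ 172 were higher and 50 lower. Of 60 genes raised by IL-4 11 were higher and 14 lower, with DNASE1L3, a secreted nuclease, up 2.62-fold (1.39 ± 0.19, adjusted p = 2.82e-04).

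**Figure D3:**
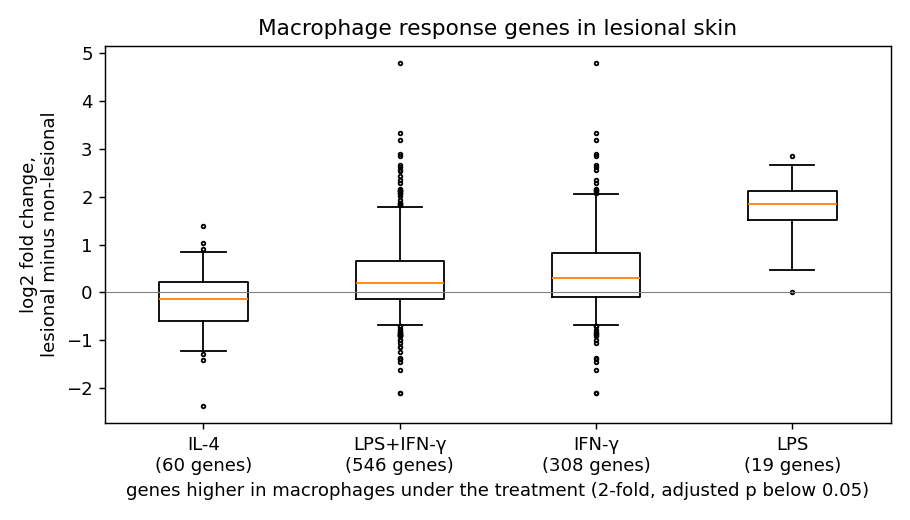
For the genes raised 2-fold or more by each macrophage treatment, the box plots show log2 fold changes between lesional and non-lesional skin (5 against 5 samples); boxes span the quartiles, the line is the median, whiskers reach the 5th and 95th percentiles and points are genes beyond them. The medians are −0.14 for IL-4, 0.20 for LPS plus IFN-γ, 0.31 for IFN-γ and 1.85 for LPS.

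Relative to all other genes these sets were shifted in lesional skin by 1.87 (LPS, adjusted p = 6.30e-14), 0.34 (IFN-γ, adjusted p = 1.50e-08) and 0.23 (LPS plus IFN-γ, adjusted p = 1.97e-06), with adjusted p = 0.0344 for each with an estimated correlation. The IL-4 set was at −0.12 and did not pass (adjusted p = 0.348), and it was at 0.01 with the submitters' values (adjusted p = 0.690) and −0.05 with the set from the fit with the replicate as a block (adjusted p = 0.649). With the 100 genes of smallest p the shifts were 0.75 for IFN-γ and 0.82 for LPS plus IFN-γ, in the opposite order. Sets defined without the 2 libraries that stood apart had adjusted p = 0.0627 for these 3 treatments with an estimated correlation. Sets of genes lowered in macrophages shifted by −0.20 for IFN-γ (190 genes, adjusted p = 0.0540, or 0.0415 with an estimated correlation) and −0.08 for LPS plus IFN-γ (519 genes, adjusted p = 0.119). The 7 lowered by IL-4 did not pass (adjusted p = 0.637; their median was −0.10 and their mean 0.20). IL-17 and TNF-α had fewer than 5 such genes. The 13 genes raised by TNF-α in the fit without the 2 libraries shifted by 0.17 (adjusted p = 0.259). Without members of the T cell, natural killer cell, dendritic cell and keratinocyte lists the shifts were 0.32 (IFN-γ) and 0.22 (LPS plus IFN-γ), with adjusted p = 0.0350 with an estimated correlation. This left 300 of 308 IFN-γ genes, 534 of 546 LPS plus IFN-γ genes and all 19 LPS genes. So few genes were removed that the shifts could change little, and the cells behind them were not tested. Differences between the shifts of the sets were not tested, and the sets are not separate signals. Of the 19 LPS genes 14 belong to the type I interferon list, which as a list was higher in lesional skin with the preset correlation. Every measured gene of that list also rose with IFN-γ and with LPS plus IFN-γ.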

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

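The tests of explanations in the next 3 paragraphs were chosen after the patterns had been seen, and the splits at the end were set up before any split had been run.

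Among the macrophage libraries 1 labelled IFN-γ and 1 labelled LPS lay outside their group on gene lists. Each lay within the range of its group's other libraries, even when widened by 1 SD, on only 3 of 7 lists. An exchange of labels between the 2 libraries is argued against, because only 1 of the 2 lay within the range of the other label's remaining libraries on the IFN-γ response list. A candidate explanation is that the library labelled LPS also received interferon-gamma, or is a combined-treatment library under another label. It lay within the range of the LPS plus IFN-γ libraries, widened by 1 SD, on 7 of 7 lists. The range of the other libraries labelled IFN-γ was not part of this test. On the IFN-γ response list the LPS library, at 1.92, also lay within their range of 1.30 to 2.35. On the NF-κB list, at 0.67, it lay below their lowest value (1.09) and below that of the LPS plus IFN-γ libraries (0.79). The test therefore cannot tell the combined treatment from IFN-γ alone. The library labelled IFN-γ stays without a tested explanation, and no sample was relabelled. The 2 libraries came from 1 donor and 1 array batch, and that batch also held the 2 samples whose labels did not decide their column. A fault of handling or labels in that batch and a trait of the donor were not tested, so both stay open.

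LPS plus IFN-γ against IFN-γ called 0 genes (limma, 350 at unadjusted p under 0.05, 0 in each alternative fit), although NF-κB genes were higher with IFN-γ alone than in control. A small rise from added LPS that missed the threshold in each replicate is argued against for the NF-κB list: 1 of 6 replicates was higher by 0.5 or more on the log2 scale, with a median difference of −0.06, a range of −0.36 to 2.26 and a second highest value of 0.10. The value of 2.26 came from the donor of the 2 libraries that stood apart, whose IFN-γ library is 1 of them. Wells labelled IFN-γ might have held LPS or a like stimulus. The NF-κB list was higher in IFN-γ than in LPS in 4 of 5 replicates, which IFN-γ acting alone would give too. In the other replicate both libraries were those that stood apart. There the IFN-γ library was at 1.31 on the IFN-γ response list, within its group's range. On the NF-κB list it was at −1.48, where the controls lay between −1.45 and −0.61. As a single library that stood apart, it does not decide the question. A stimulus in the wells cannot be told apart from an effect of IFN-γ itself on these genes, because no group measured endotoxin or blocked its receptor.

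Genes of sebaceous lipid, of muscle and sweat gland and of fat were lower in lesional skin by mean log2 changes of −2.01, −2.03 and −1.36, against −0.37 for fibroblast, −0.53 for endothelial and −0.29 for melanocyte genes. Dilution by a thicker epidermis alone is argued against, because the sebaceous lipid list fell by more than the fibroblast list, by a mean difference of −1.65 (SE 0.292, below 0 in 5 of 5 patients). This holds only if fibroblast genes changed by dilution and nothing else, which was not tested. Fewer of these structures in the lesional biopsies is a candidate explanation, with the 3 lists lower in 15 of 15 combinations of list and patient. Lower expression within the structures would give the same values, so these cannot be told apart without counts of the structures.

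A sample stood far from the rest of its group in 71 of 523 tests of a list or a named gene in a group, where chance gives about 1 in 20 (26.2 expected): 25 of 153 for list means and 46 of 370 for genes. Genes of a list and lists in a sample are not independent, so these gaps repeat each other. The values are the gap of the outermost sample to its neighbour as a share of the group's range.

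For list means, the IFN-γ response gap was 0.706 with IL-17. With LPS the gaps were IFN-γ response 0.918 and cell cycle 0.810, and with IL-4 type I interferon 0.738 and cell cycle 0.703. With TNF-α they were class II 0.694 and sterol synthesis 0.817, and in control IL-4 response 0.842 and NF-κB 0.940. With IFN-γ they were NF-κB 0.720, metallothionein 0.694, cell cycle 0.908 and T cell 0.649, and with LPS plus IFN-γ resident receptor 0.629, T cell 0.789 and B cell 0.654. In non-lesional skin they were keratinocyte activation 0.741, IL-17 and IL-23 axis 0.799, type I interferon 0.787, class I 0.730 and metallothionein 0.8286. In lesional skin they were T cell activation 0.777, endothelial 0.837, muscle and sweat gland 0.731 and natural killer cell 0.827.

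For genes, the gaps with IL-17 were CXCL9 0.795 and CD200R1 0.8286. With IFN-γ they were IDO1 0.918, ISG20 0.693, PPARG 0.649, EBI3 0.668, IL6 0.820, TNFAIP6 0.898, MT1H 0.674, MT1F 0.733, MX1 0.700, HLA-DRA 0.660, NOS2 0.666 and CLEC10A 0.774. With IL-4 they were FCER2 0.654, CDKN2B 0.701, CCL22 0.688 and CXCL10 0.699. With LPS they were CXCL9 0.940, HLA-DRA 0.720, TNF 0.746, IFITM1 0.861, ACOD1 0.961, ADAM19 0.919 and ATP6V0D2 0.883. With LPS plus IFN-γ they were CXCL10 0.637, CXCL9 0.706, HLA-DPB1 0.636, TNFAIP6 0.672, TNF 0.629 and CHST13 0.698. In lesional skin they were KRT77 0.713, CLDN5 0.773, EMCN 0.747, TEK 0.873 and KCNK6 0.797. In non-lesional skin they were PLIN1 0.797, EMCN 0.804, MFAP4 0.883, GBP5 0.814, CXCL9 0.835, HLA-B 0.761, SOCS1 0.750, SOD2 0.717, CAMP 0.804 and HERC6 0.780.

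The IFN-γ effect on the type I interferon list differed with and without LPS by a median of −1.64 on the log2 scale, by the interaction test of the report. In the LPS sample without a matched intensity column this list lay 0.74 above the highest control in the submitters' log2 values. Of 3171 tested skin probes without a gene symbol 450 were called between lesional and non-lesional skin, and no control tells how many stand for known genes.

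Each comparison was repeated on 100 splits of its samples into groups of the same sizes, the real one included, without regard to donors. The share of these splits with as many genes was under 0.05 for IFN-γ against control (3 splits, real 1315, highest other 1719). It was also under 0.05 for IL-4 (1 split, real 110, highest other 42) and LPS against control (4 splits, real 19, highest other 432). The same held for LPS plus IFN-γ against control (1 split, real 2964, highest other 1890), IFN-γ against IL-4 (2 splits, real 2505, highest other 2825) and skin (1 split, real 3490, highest other 4). For LPS plus IFN-γ against LPS 7 splits gave as many (real 1014, highest other 2619), so chance cannot be excluded for that count. Because the splits ignore donor pairs, a small share does not by itself exclude chance. Counts of 0 were met by all 100 splits, with highest others of 2 for IL-17, 11 for TNF-α, 279 for LPS plus IFN-γ against IFN-γ and 978 for the interaction. For LPS against control (432 against 19) and LPS plus IFN-γ against IFN-γ (279 against 0) a split called many more genes than the real one, which points to a structure of the samples. Whether the libraries that stood apart carry it was not tested. For the interaction the regroupings mix groups that differ by IFN-γ, so their calls can come from the groups themselves. For IFN-γ against control the split with 1719 genes was close to a mirror of the real one, with the labels of all 4 shared donors reversed. For IFN-γ against IL-4 and LPS plus IFN-γ against LPS the highest other splits exchanged 1 library per group.

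Donor IDs pair the samples, and splits that only reverse labels within donors part as many pairs as the real one. For each treatment against control, for skin and for the sets there are 16 such splits, too few for a share under 0.05. Highest other values were 0 for IL-17 and TNF-α (real 0), 1719 for IFN-γ (real 1315), 9 for IL-4 (real 110), 0 for LPS (real 19), 4 for LPS plus IFN-γ (real 2964) and 0 for skin (real 3490). They were 0.25, 0.17, 1.24 and 0.18 for the IFN-γ, IL-4, LPS and LPS plus IFN-γ sets. Comparisons of 2 treatments have 32 such splits. There the share with as many genes was under 0.05 for IFN-γ against IL-4 (1 split of 32, real 2505, highest other 1728). It was not for LPS plus IFN-γ against LPS (2 splits of 32, real 1014, highest other 1082). A share of 1 in 32 is the smallest these splits can give, so it does not by itself exclude chance. A real count of 0, as for LPS plus IFN-γ against IFN-γ (highest other 1), is met by every split, so there the splits decide nothing.

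On the 100 splits that ignore patients, the share that moved the LPS set as far in lesional skin was under 0.05 (1 split of 100, real 1.87, highest other 1.47). The same held for the IFN-γ set (2 splits, real 0.34, highest other 0.37) and the LPS plus IFN-γ set (4 splits, real 0.23, highest other 0.25). It did not hold for the IL-4 set (13 splits, real size 0.12, highest other 0.19). Patient IDs pair the samples, so a small share on these splits does not by itself exclude chance.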

How the results depend on the processing

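Fits without the 2 libraries that stood apart, also with a block or with the submitters' values, were chosen after the data were seen. Of 229 results for named genes 167 were called and 102 of these stayed called in every setting. Over all settings 3410 values kept direction and call, 267 lost and 8 gained it, and 0 turned direction. Where a count below fell under a stricter threshold, that is the construction of the setting. In the other cases, those with fewer samples included, the cause was not tested, apart from the submitters' value table. With the replicate as a block the counts were 2690 for IFN-γ, 269 for IL-4, 5 for TNF-α, 3962 for IFN-γ against IL-4 and 2345 for LPS plus IFN-γ against LPS. Array batch as a block gave 2275 for IFN-γ. Fitting only the groups compared gave 225 for IFN-γ, 57 for IL-4, 0 for LPS, 1667 for IFN-γ against IL-4 and 2 for LPS plus IFN-γ against LPS. For LPS plus IFN-γ against control, with the same group sizes as IFN-γ against control, it gave 2930 where the main fit gave 2964. A 2-fold threshold gave 556 for IFN-γ, 1167 for LPS plus IFN-γ, 908 for IFN-γ against IL-4, 374 for LPS plus IFN-γ against LPS and 841 for skin. The submitters' value table, which adds 1 control and 1 LPS sample, gave 1 for TNF-α and 1595 for LPS plus IFN-γ against LPS. The same values on the same arrays as before gave 0 and 995, so the added samples, not the values, moved these counts. Second runs gave 1 for TNF-α. Without the 2 libraries there were 2564 for IFN-γ, 17 for TNF-α, 2560 for LPS plus IFN-γ against LPS and 1 for the interaction. With the replicate block as well they were 4021 for IFN-γ, 393 for IL-4, 106 for TNF-α and 44 for LPS. They were 4711 for LPS plus IFN-γ, 4765 for IFN-γ against IL-4, 4080 for LPS plus IFN-γ against LPS and 2 for the interaction. The submitters' values without them gave 3097 for IFN-γ, 53 for TNF-α, 32 for LPS and 2940 for LPS plus IFN-γ against LPS. Of 63 list shifts called with the preset correlation, the interaction left out, 22 passed with an estimated one. Leaving out 1 replicate at a time gave 308 to 2554 (IFN-γ), 38 to 117 (IL-4), 0 to 9 (TNF-α) and 1 to 20 (LPS). It gave 1997 to 2973 (LPS plus IFN-γ), 1251 to 3098 (IFN-γ against IL-4), 89 to 2219 (LPS plus IFN-γ against LPS), 0 to 1 (interaction) and 2156 to 3988 (skin), and 0 throughout for IL-17 and for LPS plus IFN-γ against IFN-γ. Set shifts in skin then lay at 0.31 to 0.39 (IFN-γ), −0.17 to −0.09 (IL-4), 1.79 to 1.95 (LPS) and 0.23 to 0.26 (LPS plus IFN-γ). No set value could be had for IL-17 and TNF-α in the main definition. Signal over background limits genes near the detection limit: a fold against an undetected group is a lower bound.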

Other observations

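No test in this part was chosen after its result was seen. In lesional skin 3 of 7 neutrophil genes rose (4 higher adjusted over the list alone; median log2 change 0.59, adjusted p = 0.0101, and 0.315 with an estimated correlation), with the antimicrobial peptide gene CAMP up 3.42-fold (1.77 ± 0.18, n = 5 against 5, adjusted p = 6.01e-05). Among heat shock and stress genes 4 rose and 2 fell of 14 (4 and 4 adjusted over the list alone; adjusted p = 0.557), with the haem oxygenase gene HMOX1 up 2.44-fold (1.29 ± 0.18, adjusted p = 3.83e-04) and FOS down (−0.86 ± 0.24, adjusted p = 0.0187). In sterol synthesis SQLE rose 1.77-fold (0.82 ± 0.13, adjusted p = 7.12e-04) and INSIG1, which holds back the pathway, fell (−1.24 ± 0.20, adjusted p = 8.47e-04), with 1 higher and 2 lower of 10 (1 and 2 adjusted over the list alone; adjusted p = 0.848). Of 13 fibroblast genes 5 fell (5 adjusted over the list alone; median −0.43, adjusted p = 0.0626, or 0.0350 with the patient as a block, lost there with an estimated correlation at 0.5262), such as MFAP4 (−1.18 ± 0.17, adjusted p = 4.42e-04), and of 6 melanocyte genes 1 (1 adjusted over the list alone; adjusted p = 0.201). Natural killer markers rose in 2 of 6 (2 adjusted over the list alone; adjusted p = 0.142), metallothioneins in 1 of 7 (1 adjusted over the list alone; adjusted p = 0.474), and resident macrophage receptors fell in 2 of 17 (2 adjusted over the list alone; adjusted p = 0.263).

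In macrophages, sterol synthesis, B cell and neutrophil lists passed in none of the 10 macrophage comparisons, even with the preset correlation. Against control the sterol list medians were 0.01 (IL-17), 0.12 (IFN-γ), −0.19 (IL-4), 0.22 (TNF-α), 0.08 (LPS) and 0.21 (LPS plus IFN-γ). The heat shock list passed with IL-4 alone, and resident macrophage receptors with TNF-α alone, each lost with an estimated correlation. T cell and natural killer markers against control had medians of 0.11 and 0.31 with IFN-γ (adjusted p = 0.823 and 0.284), and 0.42 and 0.88 with LPS plus IFN-γ (adjusted p = 0.111 and 0.0651). Erythroid and platelet lists had too few measured genes to be tested.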
